A study of Homo sapiens with 12 samples.

How the data were processed

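Jurkat cells, a human T-cell leukaemia line, carried either a miR-21 construct or a control vector. RNA was taken from the whole lysate (Total RNA), from an immunoprecipitation (IP) with an antibody to AGO2, the Argonaute protein that holds miRNAs and their targets, and from an IP with control IgG. The 6 groups, 3 fractions by 2 constructs, had 2 replicates each, which gave 12 Affymetrix arrays. Per the labels, cells grew in RPMI medium with 10% fetal bovine serum, RNA was recovered with proteinase K and phenol-chloroform, and 1 ug of Total RNA or 100 ng of IP RNA was labelled. The labelled amount therefore differed between Total RNA and the IPs in every array.

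The deposited values are RMA values on the log2 scale, made by the authors with background correction, normalization and probe set summary. The version and settings of RMA are not given in the sources used here, nor is it stated whether the 12 arrays were normalized together. Each array had values for 54675 probe sets, of which 62 were controls. For arrays, the number of replicates limits the precision.

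Probe sets were named with the gene symbols of the platform: 42898 were listed, 41091 of them with a single gene symbol and 1801 with several, and 11721 were not listed. Of those with 1 symbol, 41037 (99.9%) matched a current gene symbol and 54 did not. Probe sets with several symbols or none were left out, and each of the 19775 named genes was represented by the probe set with the highest mean over the 12 arrays. The 12824 genes whose mean was at or above 4.02, the median over all probe sets that were not controls, were tested. The probe sets of MIR21 also list another gene and were not used. Some genes of the set fixed for naming are not analysed here.

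The tests used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8). Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3. All 12 arrays entered 1 model with a mean for each of the 6 groups, with no term for the replicate number, 6 residual degrees of freedom and limma's moderated spread (prior degrees of freedom 3.04). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. There were 9 contrasts: miR-21 construct against control vector in each fraction and as the mean of the 3 fractions; AGO2 IP against IgG IP, AGO2 IP against Total RNA and IgG IP against Total RNA, each as the mean of both constructs; and the interactions of construct with AGO2 IP against IgG IP and with AGO2 IP against Total RNA. AGO2 IP against IgG IP was also taken for each construct alone. Values are log2 differences with the standard error (SE).

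The labels number the replicates but do not say that a number marks a shared culture or day. Deviations of same-numbered arrays from their group means were therefore correlated across genes for the 15 pairs of groups. These correlations ran from 0.468 to 0.873 (median 0.601), and values from the same model with the replicate number as a block (5 residual degrees of freedom) stand beside those without it. Gene SEs in the report come from the model with the replicate block. On simulated data made from these arrays, the model without the block recovered 0% of genes moved by a log2 difference of 2 in AGO2 IP against Total RNA, and the model with the block recovered 96.0%, with 7.20 false calls per simulation on average. At a log2 difference of 1 the block model recovered 37.8% there. For the construct in AGO2 IP it recovered 72.6% at 2 and 4.60% at 1, and the model without the block 0% at both. The simulation gave each gene 1 replicate shift shared by all groups, with independent noise, as the block model assumes. The advantage of the block model was therefore built in. In the real arrays AGO2 IP minus IgG IP did not repeat between replicates, which was not simulated, so these rates need not hold there.

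Before the data were examined, the contrasts, the filter, the gene lists, the rule for named genes and the first set of alternatives were fixed. The replicate block was among those alternatives. The rule named the 10 largest rises and the 10 largest falls per contrast (5 each in the interactions) among called genes whose arrays did not overlap between the groups. The interactions required no such separation. Where fewer passed, genes with an unadjusted p under 0.01 and the same separation were added and described as not past the threshold. A few genes tied to miR-21 and up to 4 members per list were always named. After it was seen that the model without the block called no gene, the rule was applied to the model with the block, with arrays separated within each replicate. It was also applied to replicate 1 alone, where the same sign in both constructs was required instead of separated arrays.

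The 22 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast. Of these, 20 were tested. They were reported miR-21 targets, RISC and miRNA biogenesis, T cell receptor signalling, T cell activation response, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, replication-dependent histones, nuclear or noncoding RNAs, zinc finger ZNF genes, interferon response, apoptosis regulators, p53 targets, mitosis, DNA replication, cholesterol synthesis, ER chaperones and unfolded protein response, heat shock, B cell markers, epithelial and kidney cell markers, and erythroid markers. Monocyte and macrophage markers had 2 genes kept and are given as values. Mitochondrially encoded genes had 0 kept.

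Alternatives were 2 other filters on dim genes, median centring, cyclic loess, requantiling within a fraction, the mean of a gene's probe sets, every other probe set of a named gene, the groups of a contrast alone, an intensity trend, other thresholds, each array left out in turn, camera with an estimated correlation and fry, a rotation test. Analyses within each replicate, with fraction and construct as additive terms (2 residual degrees of freedom), and analyses without certain replicate 2 IP arrays were added after the data were seen, as were all alternatives applied to the model with the block.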

Results

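RNA from Jurkat cells with a miR-21 construct or a control vector was measured on 12 arrays: Total RNA, AGO2 IP RNA and IgG IP RNA, each with 2 replicates per construct. AGO2 IP RNA is the fraction bound to the miRNA effector protein, and IgG IP RNA is the antibody background. The array means were 4.39 to 4.4 on the log2 scale in replicate 1 and 5.25 to 5.27 in replicate 2. The array medians were 3.55 to 3.67 and 4.38 to 4.48. Levels so alike within a replicate number and apart between them argue against 1 joint normalization of all 12 arrays. The first principal component, which held 68.4% of the variance, separated the replicate numbers. Across genes, which are not independent replicates, the 2 Total RNA arrays of a replicate differed little by construct (SD of the difference 0.215 and 0.198). In replicate 1, AGO2 IP differed from IgG IP with an SD of 0.828 in control vector cells and 0.791 in miR-21 cells. In replicate 2 the AGO2 IP and IgG IP arrays of 1 construct were close to each other, with an SD of 0.184 (r = 0.997 across genes) for the control vector and 0.292 (r = 0.992) for miR-21. The 2 IgG IP arrays of replicate 2 differed from each other more, with an SD of 0.619 (r = 0.964).

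**Figure D1:**
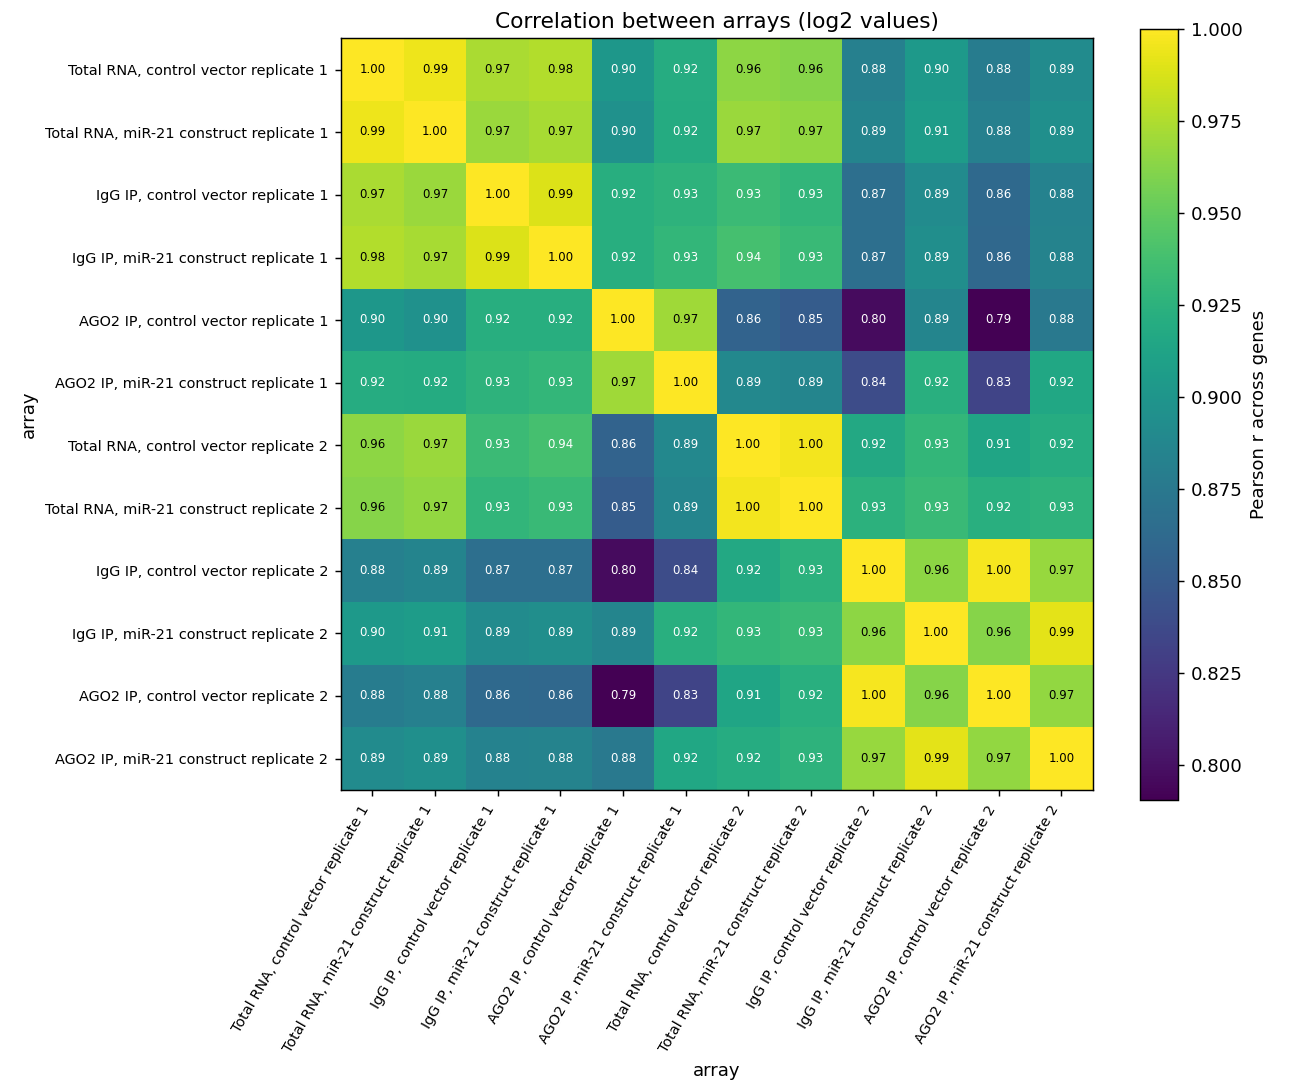
Pearson correlation across 12824 genes between each pair of the 12 arrays, labelled by fraction, construct and replicate. Arrays of replicate 2 IP RNA pair by construct (r 0.997 and 0.992), while in replicate 1 the 2 IgG IP arrays (r 0.989) and the 2 AGO2 IP arrays (r 0.970) pair by antibody.

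RNA quality and other control signals also varied between arrays. The ACTB control probe sets, read as 3' minus 5' signal, gave 1.35 and 1.38 in the Total RNA arrays of replicate 1, 4.0 in the AGO2 IP control vector array and 1.97 in the AGO2 IP miR-21 array of that replicate, and 2.18 and 2.08 in its IgG IP arrays. In replicate 2 the Total RNA arrays gave 3.53 and 3.18, the AGO2 IP arrays 2.58 and 2.08, and the IgG IP arrays 2.57 and 3.48, for control vector and miR-21 in turn. The GAPDH 3' minus 5' signal of the AGO2 IP arrays of replicate 1 was 1.95 and 0.35, in the same order. Their bioB control probe sets, which do not measure RNA quality, gave 12.1 and 9.19. The bioB values were 11.1 and 10.3 in IgG IP and 7.37 and 7.58 in Total RNA of that replicate.

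AGO2 IP RNA was compared with Total RNA to see which transcripts the purification enriched or depleted (4 arrays against 4). The labelled amount also differed between these fractions. A difference shared with IgG IP against Total RNA, given below, cannot be credited to the AGO2 antibody alone. Sharing does not show the reverse either. The IgG IP mean includes the miR-21 IgG IP array of replicate 2, which was close to the miR-21 AGO2 IP array of that replicate. With the replicate block, 604 genes rose and 1447 fell. The largest rises included the zinc finger genes ZNF14 (log2 difference 4.35 ± 0.82), ZNF124 (4.04 ± 0.66), ZNF439 (3.96 ± 0.93) and ZNF780A (3.71 ± 0.75). CFL2, a cofilin that severs actin filaments, rose by 4.25 ± 0.76, CD69, an early activation marker of lymphocytes, by 3.82 ± 0.69, and MYLIP, a ubiquitin ligase that acts on the LDL receptor, by 3.67 ± 0.71. ENPP5 (4.33 ± 0.81), GPR137B (3.76 ± 0.83) and RHEBL1 (3.72 ± 0.76) completed the 10 largest rises. Their adjusted p ran from 0.0128 for ZNF124 to 0.0262 for ZNF439. The largest falls were in FTX, a long noncoding RNA (-3.76 ± 0.22, adjusted p = 2.6e-04), RPS16P5, a ribosomal protein pseudogene (-3.61 ± 0.22), LOC100190986 (-3.43 ± 0.39), the cytokine gene MIF (-2.77 ± 0.39), the antisense RNA GABPB1-AS1 (-2.72 ± 0.30), LINC01355 (-2.58 ± 0.22) and PABPC1L (-2.49 ± 0.56). Next came the proliferation marker MKI67 (-2.48 ± 0.28), the myosin gene MYH10 (-2.36 ± 0.35) and PRKDC, the catalytic subunit of DNA-dependent protein kinase (-2.35 ± 0.26). FTX, RPS16P5, LOC100190986, MIF, GABPB1-AS1 and LINC01355 were also among the 10 largest falls named in IgG IP against Total RNA. The rule for naming required the 20 genes to move in the same direction in both replicates; ZNF14 moved by 5.57 and 3.13 and CD69 by 4.68 and 2.97. A second probe set of ZNF124 gave -0.77, and others of MYLIP gave 0.43 and 1.07. Without the block, limma called 0 genes (1230 at an unadjusted p under 0.05, smallest adjusted p 0.366). The genes then named as not past the threshold, with adjusted p = 0.366, were APP at 2.26, CD69, YAE1 at 3.66, ZNF14, E2F5 at 2.76, AP1S1 at 1.49, ACYP1 at 1.62, RAB5C at 2.76, CFL2 and BBIP1 at 2.98 on the higher side. On the lower side they were FTX, SPEN at -2.27, EP300 at -2.07, MDN1 at -2.19, SPTBN1 at -2.07, PRRC2C at -1.75, MYCBP2 at -2.01, HERC1 at -2.09, MIF and NDUFB11 at -2.27. Other probe sets of APP gave 0.57 and 0.16, and 7 of SPTBN1 gave -0.67 to 0.21. Within replicate 1, 1668 genes were called higher and 2987 lower, and within replicate 2, 2027 higher and 2482 lower. Of these, 572 were higher in both and 1105 lower in both, against 264 and 578 for independent lists. Median centring moved the median of all genes from -0.05 to 0.14 and the share of called genes that were higher from 29.4% to 59.2% (1017 higher, 701 lower), so the split by direction follows the scaling. The count of 2051 fell to 2 without the AGO2 IP miR-21 array of replicate 2, to 68 without that of replicate 1, to 57 and 53 without the control vector and miR-21 Total RNA arrays of replicate 2. It fell to 1197 without the miR-21 Total RNA array of replicate 1 and to 1029 without the AGO2 IP control vector array of replicate 1.

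**Figure D2:**
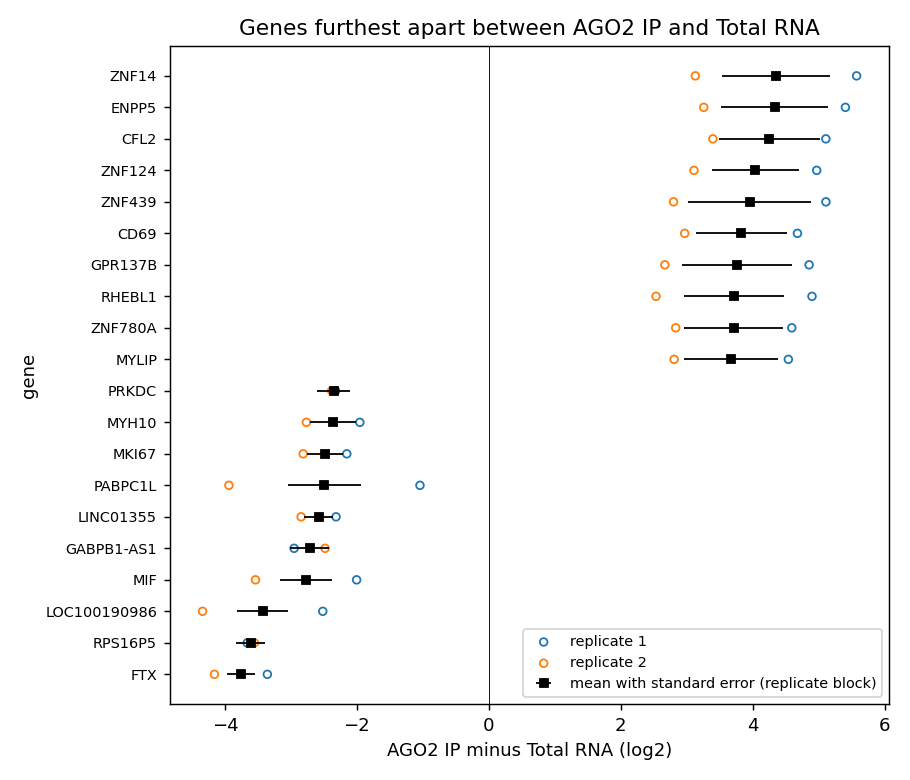
Log2 difference between AGO2 IP and Total RNA for the 20 genes named with the block, with a point for each replicate and the mean with its SE from the model with the replicate block. ZNF14 had the largest mean rise (4.35) and FTX the largest mean fall (-3.76).

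Several gene groups moved against the other genes in AGO2 IP against Total RNA, whose median was -0.05. Of 58 cytosolic ribosomal protein genes, 20 fell and 0 rose with the block (25 and 0 adjusted over the list alone), with a median of -0.46; RPL39L (-1.69), RPL12 (-1.64), RPL39 (-1.46) and RPL32 (-1.41) fell most. The list's adjusted p was 8.2e-08 without and 1.1e-05 with the block, and adjusted p = 0.569 with an estimated correlation and the block. Of 69 nuclear-encoded oxidative phosphorylation genes, 19 fell and 1 rose (30 and 2 adjusted over the list alone), with a median of -0.64; NDUFB11 (-2.27), NDUFS7 (-2.03) and UQCR11 (-1.85) fell, while SDHC, a subunit of complex II, rose by 1.90. Its adjusted p was 2.6e-07 without and 9.4e-04 with the block, and adjusted p = 0.596 with an estimated correlation and the block; within replicate 1 the adjusted p was 0.286 and within replicate 2 2.2e-07. Of 21 replication-dependent histone genes, whose mRNAs lack poly(A) tails, 8 fell and 0 rose (11 and 1 adjusted over the list alone), with a median of -0.73; they included H1-2 (-2.0), H3C2 (-1.18), H4C11 (-1.13) and H2AC14 (-1.03). The adjusted p was 4.2e-04 without and 0.00335 with the block, and adjusted p = 0.374 with an estimated correlation and the block. Of 37 DNA replication genes, 14 fell and 0 rose (14 and 0 adjusted over the list alone), among them MCM10 (-1.61), MCM2 (-1.44), MCM4 (-1.32) and TK1 (-1.18). That list's median was -0.32, with adjusted p = 0.0330 without the block and 0.0624 with it, and adjusted p = 0.988 and 0.374 with an estimated correlation.

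On the higher side, 5 of 17 T cell activation response genes rose and 0 fell with the block (6 and 0 adjusted over the list alone), among them CD69, IER3 (2.54), the phosphatase gene DUSP5 (1.63) and the costimulatory receptor gene ICOS (1.39). The list's median was 0.63, 1.02 in replicate 1 and 0.02 in replicate 2, with adjusted p = 4.2e-04 without and 0.00217 with the block, adjusted p = 0.374 with an estimated correlation and the block, and adjusted p = 0.246 within replicate 2. Of 352 zinc finger ZNF genes, 46 rose and 24 fell (61 and 35 adjusted over the list alone); the median was 0.21, with adjusted p = 7.4e-05 without and 9.4e-04 with the block, and adjusted p = 0.569 with an estimated correlation and the block. Of 20 p53 target genes, 3 rose and 0 fell (6 and 0 adjusted over the list alone): SESN1 (2.06), the death receptor gene FAS (1.57) and TP53INP1 (1.16). Their median was 0.45, with adjusted p = 0.00442 without and 0.00252 with the block, and adjusted p = 0.374 with an estimated correlation and the block. Without the block the estimated correlation gave adjusted p = 0.988 for these lists, and members called adjusted over the list alone numbered 3: 1 T cell activation response gene and 2 oxidative phosphorylation genes. Each list's direction relative to the other genes was the same under cyclic loess. Median centring shifts all genes of an array alike and cannot change that direction. The ribosomal protein, oxidative phosphorylation, histone, T cell activation and p53 lists were also called in the same direction in IgG IP against Total RNA, given below. Without the control vector AGO2 IP and miR-21 IgG IP arrays of replicate 2, the oxidative phosphorylation, histone, T cell activation and p53 lists were no longer called there. Whether these differences are shared with the antibody background is therefore not settled.

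**Figure D3:**
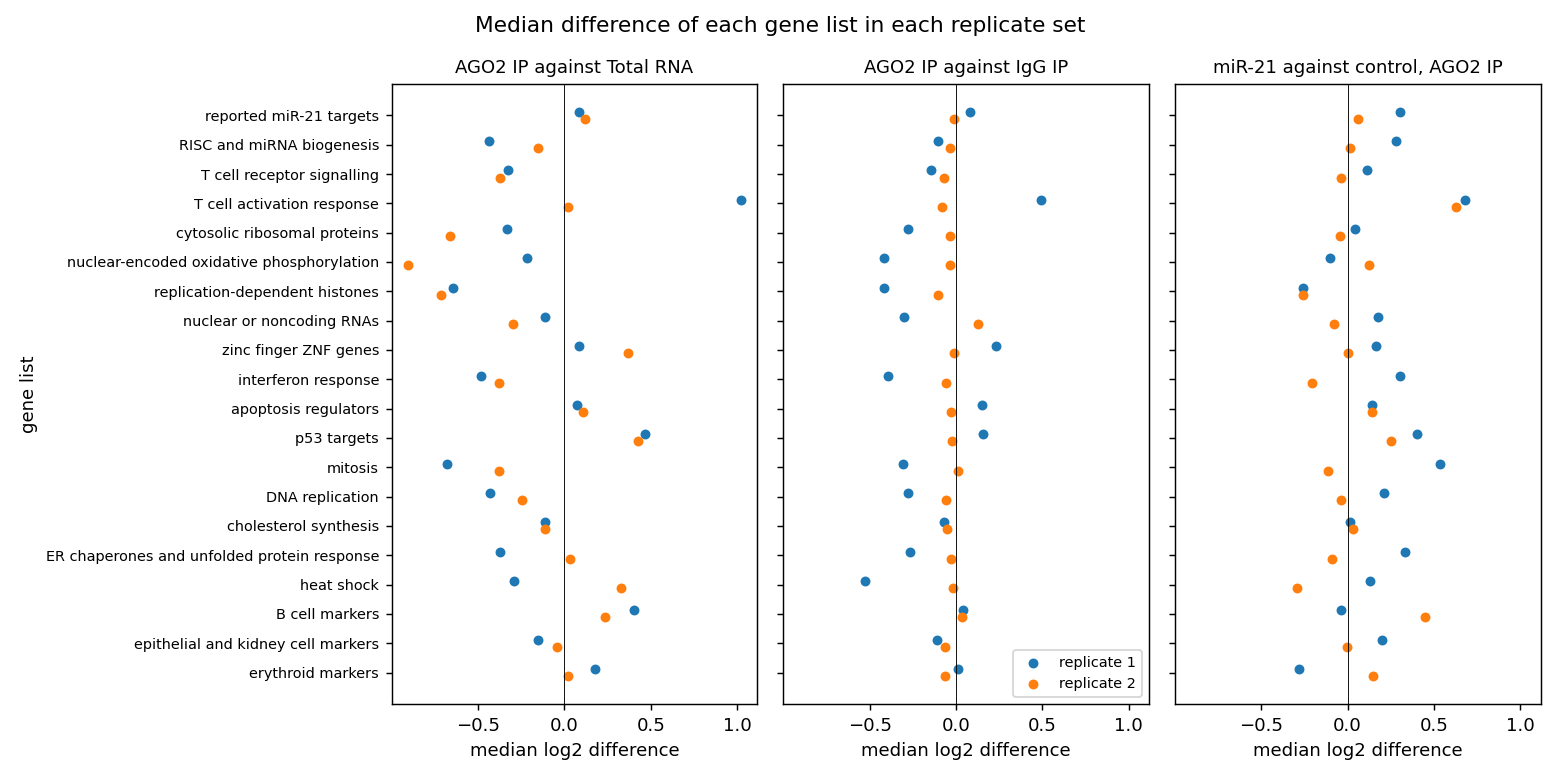
Median log2 difference of each gene list in replicate 1 and replicate 2, in AGO2 IP against Total RNA, AGO2 IP against IgG IP and miR-21 construct against control vector in AGO2 IP. The T cell activation response list lay at 1.02 in replicate 1 and 0.02 in replicate 2 in AGO2 IP against Total RNA.

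Reported miR-21 targets moved in both directions in AGO2 IP against Total RNA: of 41 genes, 5 rose and 4 fell with the block (5 and 4 adjusted over the list alone). The receptor gene TGFBR2 rose by 2.25, SESN1 by 2.06 and the tropomyosin gene TPM1 by 1.77, while the receptor gene BMPR2 fell by 1.72. Against IgG IP over both replicates, where no gene was called, they lay at 1.39, 1.33, 0.71 and -0.39 in turn. The list's median was 0.10 (adjusted p = 0.235). Of 30 RISC and miRNA biogenesis genes 4 fell (4 adjusted over the list alone), EDC4 (-1.29), DDX17 (-0.99), DROSHA (-0.92) and AGO2 itself (-0.81, adjusted p = 0.0426); the list's median was -0.31 (adjusted p = 0.563).

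Other lists were not called in this comparison as sets, though some members were. Of 32 interferon response genes 1 rose and 6 fell (3 and 10 adjusted over the list alone; median -0.49, adjusted p = 0.193). IRF9 rose by 3.11, while IFITM1 (-1.50), ISG15 (-1.40) and IFI35 (-1.15) fell. Of 30 apoptosis regulators 5 rose and 3 fell (6 and 3 adjusted over the list alone; median 0.14, adjusted p = 0.270). CASP8 rose by 2.40, MCL1 by 1.67, FAS by 1.57 and BCL2L11 by 1.39. Of 30 mitosis genes 2 rose and 7 fell (2 and 10 adjusted over the list alone; median -0.35, adjusted p = 0.318, 0.0709 with the block). CDC25C rose by 2.22 and CCNA2 by 1.54, while the kinetochore genes CENPE (-2.18) and CENPF (-1.91) fell. Of 28 ER chaperone and unfolded protein response genes 5 rose and 3 fell (6 and 5 adjusted over the list alone; median -0.21, adjusted p = 0.660). CHAC1 rose by 2.92, DNAJB9 by 2.76 and DDIT4 by 1.18, while P4HB fell by 1.32. Of 19 heat shock genes 2 rose and 2 fell (2 and 2 adjusted over the list alone; median -0.13, adjusted p = 0.877). DNAJB4 rose by 2.33 and DNAJA1 by 1.15, while STIP1 (-1.21) and CCT3 (-0.93) fell. Of 18 cholesterol synthesis genes 1 rose and 2 fell (2 and 3 adjusted over the list alone; median -0.32, adjusted p = 0.769). HMGCS1 rose by 1.61, while HSD17B7 (-1.06) and FDPS (-0.92) fell. CD3E (-0.74), PTPRC (-0.74) and CD5 (-0.73) fell among 36 T cell receptor signalling genes (0 adjusted over the list alone; median -0.38, adjusted p = 0.212). TUG1 (-0.97) fell among nuclear or noncoding RNAs (median 0.04, adjusted p = 0.965), and GATA3 (-0.80), which T cells also express, among epithelial and kidney cell markers (median -0.07, adjusted p = 0.907). B cell markers (median 0.30, adjusted p = 0.235), with POU2AF1 at 0.79 and BLK at -0.30, and erythroid markers (median 0.13, adjusted p = 0.693), with HBB at -0.35, had no called member. The 2 monocyte and macrophage markers kept had a median of -0.27, with CSF1R at 0.17 and CST3 at -0.71.

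IgG IP RNA was compared with Total RNA as the measure of the antibody background (4 arrays against 4). With the replicate block, 38 genes rose and 208 fell. The rises were led by TAF15, an RNA-binding protein gene (3.17 ± 0.65, adjusted p = 0.0490), and APP, the amyloid precursor gene (2.37 ± 0.27, adjusted p = 0.00815), followed by the nuclear lamin gene LMNB1 (2.02), NPM3 (2.0), PIN4 (1.92), SDHC (1.73), ACYP1 (1.65), AP1S1 (1.64), NDUFAF2 (1.58) and SEM1 (1.57). The falls were led by LOC100190986 (-3.56), FTX (-3.21 ± 0.22, adjusted p = 9.8e-04) and RPS16P5 (-3.10), followed by LINC01355 (-2.50), MIF (-2.38), LOC285097 (-2.24), the ubiquitin ligase gene UBR4 (-2.22), ANKRD36B (-2.19), GABPB1-AS1 (-2.13) and HERC2 (-2.13). Other probe sets moved differently for TAF15 (-2.75, -1.50 and -0.20), APP (0.53 and -0.17), PIN4 (-0.42), SDHC (-0.27 and -0.59), UBR4 (-0.00 to 0.36 over 4) and HERC2 (0.13). Without the block, limma called 0 genes (437 at an unadjusted p under 0.05). The genes then named as not past the threshold also included SLC39A1 (1.28), INHBC (1.18), RAB30-DT (1.5), KSR2 (-1.76), SPEN (-2.0), MDN1 (-2.01), MYCBP2 (-1.93), SPTBN1 (-1.84), HERC1 (-1.95) and UTP20 (-1.58). Within replicate 1, 99 genes were called higher and 384 lower, and within replicate 2, 1885 higher and 2128 lower. Of these, 54 were higher in both and 176 lower in both, against 14.6 and 63.7 for independent lists. Median centring moved the median of all genes from -0.01 to 0.15 and the share of called genes that were higher from 15.4% to 38.3% (54 higher, 87 lower). The count of 246 was 3 without any of the control vector IgG IP array of replicate 1, the miR-21 IgG IP array of replicate 2 and the control vector and miR-21 Total RNA arrays of replicate 2. It was 4 without the control vector IgG IP array of replicate 2, and 54 without the miR-21 IgG IP array of replicate 1. It was 76 and 134 without the miR-21 and control vector Total RNA arrays of replicate 1, 78 without either miR-21 AGO2 IP array, 563 without either control vector AGO2 IP array, and 51 without the control vector AGO2 IP and miR-21 IgG IP arrays of replicate 2 together.

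Ribosomal protein genes were lower in IgG IP against Total RNA as a group (median -0.40; 0 rose and 1 fell, RPL12 at -1.38; 0 and 19 adjusted over the list alone), with adjusted p = 1.2e-07 without and 4.7e-05 with the block and adjusted p = 0.554 with an estimated correlation and the block. Oxidative phosphorylation genes had a median of -0.45, 0.10 in replicate 1; SDHC rose while NDUFB11 (-2.04) and NDUFS7 (-1.67) fell (5 and 18 adjusted over the list alone), with adjusted p = 2.1e-07 without and 0.00610 with the block and adjusted p = 0.753 with an estimated correlation and the block. Replication-dependent histone genes had a median of -0.42 (adjusted p = 0.00959 without and 0.0346 with the block), although H4C8 rose by 1.24 (1 and 6 adjusted over the list alone). T cell activation response genes (median 0.25, adjusted p = 0.0411, ICOS up by 1.26) and p53 targets (median 0.17, adjusted p = 0.0411, GADD45A at 1.28 and BAX at 1.08 not past the threshold) were higher as groups, each with adjusted p = 0.0346 with the block. With an estimated correlation and the block, adjusted p = 0.535 for the histone, T cell activation and p53 lists. DNA replication genes were lower without the block (median -0.18, adjusted p = 0.0457) and not with it (adjusted p = 0.0790), and GINS4 fell by 1.01. With the block alone, RISC and miRNA biogenesis genes (median -0.27, adjusted p = 0.0388, 0.0578 without) and mitosis genes (median -0.32, adjusted p = 0.0346, 0.203 without) were also lower, with CENPE (-1.90), CENPF (-1.64), ASPM (-1.13) and TOP2A (-1.03) falling. With an estimated correlation and the block, adjusted p = 0.535 for both lists and for DNA replication. Without the block the estimated correlation gave adjusted p = 0.971 for these lists. Without the control vector AGO2 IP and miR-21 IgG IP arrays of replicate 2, the oxidative phosphorylation (adjusted p = 0.181), histone (0.188), T cell activation (0.126) and p53 (0.196) lists were no longer called. The zinc finger genes ZNF573 (-2.06), ZNF431 (-1.64), ZNF81 (-1.47) and ZNF587 (-1.34) fell.

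AGO2 IP was compared with IgG IP, the comparison that measures what the AGO2 antibody recovered beyond background (4 arrays against 4). Within 1 replicate the arrays of the 2 constructs stand in for replicates, so calls there do not measure spread between replicates. In replicate 1, 1600 genes were called higher and 1480 lower in AGO2 IP. The highest were ZNF439 (5.42), ENPP5 (4.92), ZNF700 (4.77), ZNF14 (4.65), ZNF658 (4.63), GPR137B (4.63), SOCS1 (4.61), a suppressor of cytokine signalling, ZNF180 (4.58), ZNF780A (4.51) and CFL2 (4.38). The lowest were the chromatin remodeller CHD2 (-2.74), USB1 (-2.28), LSM14A (-1.98), WIPF1 (-1.85), PMS2P5 (-1.84), HMGN5 (-1.72), ANAPC10 (-1.66), the SWI/SNF ATPase gene SMARCA4 (-1.59), GALK2 (-1.53) and LCP2 (-1.53), an adaptor of T cell receptor signalling. In replicate 2, limma called 0 genes (47 at an unadjusted p under 0.05), and ZNF439 and ENPP5 lay at 0.09 and 0.40. CD69 lay at 4.02 in replicate 1 and 0.16 in replicate 2. Across genes the differences of the 2 replicates had a correlation of -0.0017, and of the genes called higher in replicate 1, 47.0% were above 0 in replicate 2, against 43.9% of all genes.

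**Figure D4:**
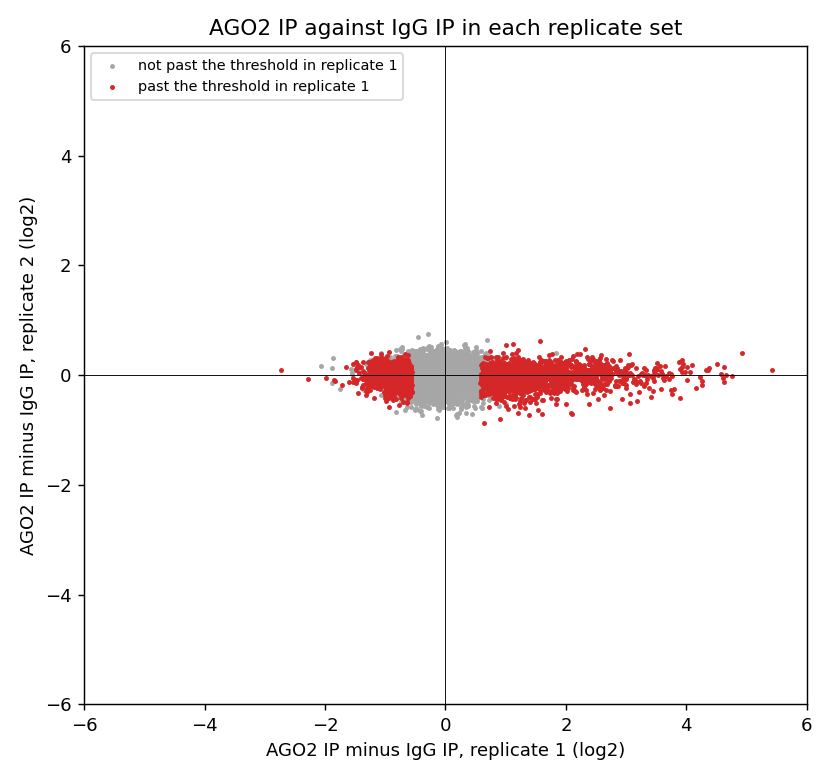
Log2 difference between AGO2 IP and IgG IP, averaged over constructs, in replicate 1 (x axis) and replicate 2 (y axis) for 12824 genes. Genes spread along the replicate 1 axis up to 5.42 (ZNF439), where replicate 2 gave 0.09.

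Over both replicates, limma called 0 genes in AGO2 IP against IgG IP without the block (29 at an unadjusted p under 0.05) and 0 with it (663). Genes named as not past the threshold with the block (adjusted p = 0.819) were FCHO2 (1.05), SOCS5 (1.08), USP44 (1.09) and MATCAP2 (1.39). With the block and without the control vector AGO2 IP and miR-21 IgG IP arrays of replicate 2, 763 genes were called higher and 188 lower. Those 2 arrays were chosen because they did not show the replicate 1 difference between the antibodies, so the counts and list values without them are descriptive and do not test that difference. They also leave 1 array in each of those 2 groups, whose spread is taken from the other groups. In control vector cells alone, 0 genes were called without the block (0 at an unadjusted p under 0.05) and 0 with it (68), with ZNF561-AS1 at 0.98 not past the threshold; without the same 2 arrays, with the AGO2 IP arm at 1 array, 5 were called higher and 3 lower. In miR-21 cells alone, 0 genes were called without the block (0) and 0 with it (293), and CNST (1.33), SOCS5 (1.71), FZD6 (2.10) and FOLR1 (-1.16) were among those named as not past the threshold.

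As a group, the zinc finger ZNF genes were higher in AGO2 IP than in IgG IP (median 0.13, 228 of 352 above 0, adjusted p = 6.4e-08 without and 7.0e-08 with the block), as were T cell activation response genes (median 0.16, adjusted p = 2.5e-04 and 0.00615) and p53 targets (median 0.10, adjusted p = 0.0464 and 0.0388). Histone genes (median -0.25, adjusted p = 0.0105 and 0.0219), oxidative phosphorylation genes (median -0.23, adjusted p = 0.0155 and 0.0388) and ribosomal protein genes (median -0.15, adjusted p = 0.0113 and 0.0388) were lower, the last with a sign that flipped under cyclic loess (median 0.01). No member was called, and with an estimated correlation adjusted p = 0.977 without the block and 0.645 to 0.727 with it. Without the control vector AGO2 IP and miR-21 IgG IP arrays of replicate 2, the zinc finger (adjusted p = 4.5e-05) and T cell activation (0.00314) lists were called, and the p53 (0.113), histone (0.102), oxidative phosphorylation (0.224) and ribosomal (0.113) lists were not. The medians were further from 0 in replicate 1 (zinc finger 0.23, T cell activation 0.49, histones -0.42, oxidative phosphorylation -0.42, ribosomal -0.28), and within replicate 2 the adjusted p ran from 0.739 to 0.959. Reported miR-21 targets gave adjusted p = 0.0559 without and 0.0813 with the block over both constructs. In miR-21 cells alone they were higher in AGO2 IP than in IgG IP as a group (27 of 41 above 0, adjusted p = 0.00646 without and 0.00744 with the block; adjusted p = 0.961 and 0.471 with an estimated correlation), with a median of 0.06, 0.34 in replicate 1 and -0.04 in replicate 2. Without the same 2 arrays their adjusted p was 0.00110. In miR-21 cells alone the zinc finger (adjusted p = 1.7e-07), T cell activation (7.2e-05) and p53 (0.0261) lists were also higher, and the histone (0.00184), oxidative phosphorylation (0.00694) and ribosomal (0.0139) lists lower, each also called with the block (adjusted p = 0.471 to 0.792 with an estimated correlation and the block). In control vector cells alone the zinc finger (adjusted p = 3.7e-05, 6.5e-05 with the block) and T cell activation (0.0248, 0.199 with the block) lists were higher, with adjusted p = 0.986 and 0.905 with an estimated correlation. For miR-21 targets in control vector cells the adjusted p was 0.569. The interaction, which tests whether the constructs differed, gave adjusted p = 0.127 without and 0.139 with the block. With the block and without those 2 arrays the interaction was called at the preset correlation. That fit leaves 1 array in 2 of the groups and was not run with an estimated correlation, so it is descriptive.

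The miR-21 construct was compared with the control vector in AGO2 IP RNA (2 arrays against 2). The aim was to find transcripts that gained or lost AGO2-bound RNA in cells with the construct. Whether the construct raised miR-21 was not checked here, as the MIR21 probe sets were not used. No gene passed the threshold: limma called 0 without the block (11 at an unadjusted p under 0.05) and 0 with it (353). With the block and the arrays of these 2 groups alone it called 49, 48 higher and 1 lower. That fit has 1 residual degree of freedom and includes the control vector AGO2 IP array of replicate 2 set aside above, so its count is descriptive. In simulated data the block model recovered 4.60% of genes moved by a log2 difference of 1 in this comparison, so changes of that size were mostly not detectable. The genes named as not past the threshold included ZMYM6 (1.40 ± 0.26), the adhesion receptor gene ADGRD1 (2.38 ± 0.48), SRPX (1.76), APPL2 (1.56), the transcriptional repressor gene BCL6 (1.60), ALG1 (1.34), HOXC6 (1.12), CEP192 (1.38), GAREM1 (1.57) and MED18 (1.84). Lower were SLC15A2 (-0.96), TUBGCP5 (-0.97) and FOLR1 (-0.89), also not past the threshold. Reported miR-21 targets had a median of 0.24 with 29 of 41 above 0 (adjusted p = 0.20 without and 0.147 with the block; 0 called, 0 adjusted over the list alone), with TGFBR2 at 1.14, RECK at 1.07, LRRFIP1 at -0.70 and MSH6 at -0.35. The T cell activation response list was higher, with a median of 0.68 against 0.07 for the other genes and 17 of 17 above 0, among them DUSP2 (1.75; 0.07 in replicate 1 and 3.44 in replicate 2) and DUSP5 (1.69). Its adjusted p was 1.4e-05 without and 1.4e-04 with the block, adjusted p = 0.976 and 0.450 with an estimated correlation, and 0.266 without the 2 replicate 2 arrays named above (median 0.33). Histone genes were lower (median -0.23, adjusted p = 0.00101 and 0.00182, 0.0365 without those arrays; adjusted p = 0.976 and 0.450 with an estimated correlation), with H2BC9 at -0.98 and H4C8 at -0.65. RISC and miRNA biogenesis genes were higher (median 0.26, adjusted p = 0.0236 and 0.0414, 0.159 without those arrays; adjusted p = 0.976 and 0.450 with an estimated correlation). Members not past the threshold were MOV10 at 1.03 and XPO5 at 0.99. With the block alone p53 targets (adjusted p = 0.0414, 0.180 without), mitosis genes (0.0391, 0.102 without; medians 0.54 and -0.11 in the replicates) and B cell markers (0.0391, 0.102 without; 2 higher adjusted over the list alone) were called as groups. With an estimated correlation and the block, adjusted p = 0.615 for p53 targets and mitosis genes and 0.450 for B cell markers. Without those arrays the preset correlation gave adjusted p = 0.154 for p53 targets, 0.00406 for mitosis and 0.441 for B cell markers. The AGO2 IP control vector array of replicate 1 had the ACTB 3' minus 5' difference of 4.0 given above. Median centring moved the median of all genes from 0.07 to -0.11.

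In Total RNA, where the comparison gives the change in transcript level, the mitosis genes were higher with miR-21 as a group (median 0.15, 27 of 30 above 0, adjusted p = 0.0336 without and 8.1e-04 with the block), with the kinase gene AURKA at 0.35 and UBE2C at 0.33. With an estimated correlation adjusted p = 0.990 and 0.859, and the medians were 0.29 in replicate 1 and 0.00 in replicate 2. No gene passed: limma called 0 without the block (0 at an unadjusted p under 0.05) and 0 with it (3). Reported miR-21 targets gave adjusted p = 0.955.

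In IgG IP, limma called 0 genes for the construct without the block (4 at an unadjusted p under 0.05) and 0 with it (123). The genes named as not past the threshold included the T-cell leukaemia gene LMO1 (1.05), CCDC142 (1.07), LLGL2 (1.14), the hyaluronan synthase gene HAS3 (1.00), GPR39 (0.92), AHRR (1.04), ARHGEF39 (0.97), TMEM38A (1.17), KLHL26 (1.13), ZNHIT2 (0.76). Lower, also not past the threshold, were RAB31 (-1.19), ZNF431 (-0.99) and CYP1B1 (-1.01). T cell activation response genes were higher here too (median 0.44; 0.12 in replicate 1 and 0.72 in replicate 2), with adjusted p = 0.00449 without and 0.00763 with the block, adjusted p = 0.991 and 0.981 with an estimated correlation, and 0.630 without the same 2 replicate 2 arrays. Reported miR-21 targets gave adjusted p = 0.797. With the block and without those 2 arrays they were lower at the preset correlation. That fit leaves 1 miR-21 IgG IP array and was not run with an estimated correlation, so it is descriptive. Median centring moved the median of all genes from 0.04 to -0.10.

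As the mean of the 3 fractions (6 arrays against 6), limma called 0 genes for the construct without the block (10 at an unadjusted p under 0.05) and 0 with it (306). ADGRD1 (1.21), BCL6 (0.87), CDKN1C (0.68), an inhibitor of cyclin-dependent kinases, ALOX5AP (1.22) and RAB31 (-0.64) were among the genes named as not past the threshold. T cell activation response genes were higher (median 0.39, adjusted p = 9.5e-06 without and 6.7e-05 with the block), histone genes lower (median -0.11, adjusted p = 0.00147 and 0.00450), and RISC and miRNA biogenesis genes higher without the block (median 0.17, adjusted p = 0.0195, 0.0526 with it). Mitosis genes were higher with the block (adjusted p = 0.00797, 0.0786 without). Their median became -0.02 under median centring, which shifts all genes alike and leaves the list's place among them unchanged. With an estimated correlation adjusted p = 0.981 without the block and 0.477 to 0.526 with it. Without the same 2 replicate 2 arrays the T cell activation and histone lists gave adjusted p = 0.171 and the mitosis list 2.9e-06. Median centring moved the median of all genes from 0.04 to -0.08.

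The interactions ask whether the construct changed AGO2 recovery relative to IgG IP or to Total RNA. Relative to IgG IP, limma called 0 genes without the block (0 at an unadjusted p under 0.05) and 0 with it (39), no list was called over all 12 arrays, and GPR39 (-1.27) was named as not past the threshold. Relative to Total RNA, 0 genes were called without the block (0) and 0 with it (60), and ZMYM6 (1.39), HOXC6 (1.37) and ADGRD1 (2.29) were named as not past the threshold. The T cell activation response list was higher in AGO2 IP beyond Total RNA with miR-21 (median 0.58, 17 of 17 above 0), with adjusted p = 2.1e-04 without and 7.9e-04 with the block, adjusted p = 0.978 and 0.686 with an estimated correlation, and 0.340 without the same 2 replicate 2 arrays. Median centring moved the median of all genes from 0.07 to -0.09. The histone list was lower (median -0.17, adjusted p = 0.0126 and 0.0211, 0.0671 without those arrays; adjusted p = 0.978 and 0.686 with an estimated correlation), with H2BC9 at -0.88 and H1-2 at 0.89.

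Among the genes always named, none passed for the construct in AGO2 IP RNA: AGO2 gave 0.95 ± 0.32, RECK, an inhibitor of matrix metalloproteinases, 1.07 ± 0.52, SPRY1 0.67 ± 0.33, SPRY2 0.35 ± 0.28, CDC25A 0.31 ± 0.43, TIMP3 0.18 ± 0.31, TPM1 -0.03 ± 0.47 and RASGRP1 -0.06 ± 0.27, each with adjusted p = 1.00 with the block. The 4 other probe sets of RECK went the other way, from -0.83 to -0.28. In Total RNA, AGO2 gave 0.08 ± 0.32 and RECK -0.03 ± 0.52. In AGO2 IP against Total RNA with the block, TPM1 rose by 1.77 and AGO2 fell by 0.81. RECK at 1.15 (adjusted p = 0.0640) and CDC25A at 0.88 (adjusted p = 0.0796) did not pass. IgG IP against Total RNA gave 1.05 for TPM1, -0.72 for AGO2, 0.19 for RECK and 0.63 for CDC25A, none past the threshold. VMP1, PDCD4 and FASLG had dim probe sets below the filter and were not tested.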

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

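The tests of explanations in this part were chosen after the results were seen, except the interactions and the count of other splits, which were set before.

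With camera's preset correlation, a difference between groups was called for the T cell activation response list, whose construct difference was 0.583 higher (log2, median) in AGO2 IP than in Total RNA, and for replication-dependent histones, at -0.167. Neither was called with an estimated correlation (adjusted p = 0.978 without and 0.686 with the block) or without the 2 replicate 2 arrays in doubt (0.340 and 0.0671). Probe sets without a gene name were outside the comparisons, and 508 of 3066 were called in AGO2 IP against Total RNA with the replicate block, 59 higher and 449 lower, or 16.6%, against 14.6% of probe sets with a single name and 209 of 1118 with several. The poly-A labelling control dap, also outside the comparisons, gave signal in the 2 Total RNA arrays of replicate 1 (7.98 and 8.32). It gave none above background in its 4 IP arrays (2.11 to 2.48, below the array medians of 3.56 to 3.67). The size of the gap of 5.90 between the means is set by the background. Signal in 1 fraction and none in the IPs is still a difference between them in replicate 1, whose cause was not tested. In replicate 2 the means were 6.60 in Total RNA and 6.49 in the IPs.

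In replicate 2, the IP arrays paired by construct instead of by antibody. A construct effect that repeats between replicates is argued against, since the larger correlation across genes of the construct difference between replicates was 0.0721. An exchange of the labels of the control vector AGO2 IP array and the miR-21 IgG IP array may account for the pairing: the replicate 2 construct differences followed the replicate 1 AGO2 minus IgG difference with r of at least 0.593 across genes (the other 0.616). Low AGO2 recovery in one IP with AGO2-type RNA in one IgG IP cannot be told apart from it, because the miR-21 IgG IP array lay 99.7% of the way to the AGO2 type, where a complete mix and an exchange give the same value. The arrays were kept under their labels in the comparisons; among the other splits counted for AGO2 IP against IgG IP with the block, the one that matches this exchange gave 3953 genes against 0 for the given labels, which is not independent evidence, since the exchange was proposed from the same arrays.

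The T cell activation response list was called higher with the miR-21 construct in IP RNA at the preset correlation, with no member called and with adjusted p = 0.976 and 0.450 in AGO2 IP and 0.991 and 0.981 in IgG IP, without and with the block, at an estimated correlation. In AGO2 IP, the list exceeded other genes by 0.558 in replicate 1 alone, so that excess does not come from the replicate 2 arrays in doubt. It lay above 100% of 10000 random lists matched on level. Such lists ignore correlation among members, the list was picked with replicate 1 included, and each group has 1 array there. Whether the arrays in doubt are the whole cause of the call is therefore not decided. Without the arrays in doubt, with fewer arrays and a median of 0.33 instead of 0.68, the list was not called. In IgG IP the arrays in doubt may account for the call, as replicate 1 alone gave 0.0958. RNA quality of the control vector AGO2 IP array of replicate 1 cannot be told apart from the construct, since its ACTB 3' minus 5' difference exceeded that of its partner by 2.03 and each group has 1 array there. In replicate 1 the construct difference in AGO2 IP beyond that in Total RNA exceeded other genes by 0.457 (12 of 17 members above 0, above 99.9% of random lists). With the same limits, higher steady-state mRNA as the whole cause in AGO2 IP is not decided. A part also stays open, with a Total RNA excess of 0.150 in replicate 1 and -0.0118 in replicate 2.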

How the results depend on the processing

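The values with the 2 or 4 replicate 2 IP arrays left out, within 1 replicate, and of each alternative applied to the model with the replicate block were chosen after the results were seen; the others were planned.

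Without the block 0 genes were called in each comparison. For AGO2 IP against Total RNA the replicate block gave 2051, median centring 1, cyclic loess 1, replicate 1 alone 4655 and replicate 2 alone 4509; for IgG IP against Total RNA these were 246, 1, 1, 483 and 4013. For AGO2 IP against IgG IP replicate 1 alone gave 3080. The cause was not tested. With the replicate block, the construct in AGO2 IP gave 49 genes (48 higher, 1 lower) with the groups of the contrast alone, a fit with 1 residual degree of freedom. AGO2 IP against Total RNA gave 3261 at adjusted p under 0.1, and 2 to 3051 with 1 array left out. IgG IP against Total RNA gave 148 with the stricter filter, 141 with median centring, 129 with the mean of probe sets, 709 at adjusted p under 0.1, 51 without the control vector AGO2 IP and miR-21 IgG IP arrays of replicate 2, and 3 to 563 with 1 array left out. Without those 2 arrays AGO2 IP against IgG IP gave 951, and 8 in control vector cells.

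Without the 4 IP arrays of replicate 2, the block model has 1 residual degree of freedom, from Total RNA arrays alone, and assumes that lone IP arrays vary like those. It gave 3300 genes for the construct in AGO2 IP, 87 in IgG IP, 1647 over the 3 fractions, 7058 for AGO2 IP against IgG IP (6264 in control vector and 4684 in miR-21 cells), 8093 and 4872 for AGO2 IP and IgG IP against Total RNA, and 1273 and 1376 in the interactions with IgG IP and Total RNA.

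Of the 29 list calls over the 9 contrasts, 0 were called with an estimated correlation and 0 with fry; 26 remained with the replicate block, 25 without a filter, 25 with the mean of probe sets and 11 with the block and without the 2 arrays named above. Of the values of named genes, 124 stayed on their side of the threshold with the block and 67 passed it. With the mean of probe sets 136 moved by less than their SE in the model without the block and 35 by more, and other probe sets gave 150 and 167. Changes of sign were not counted apart. The miR-21 seed site shift was not run, with its alternatives (8mer sites only, any transcript, estimated correlation, 3' UTR length match, replicate block). Dim signal limits VMP1, PDCD4 and FASLG, which lay below the filter.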

Other observations

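The test of miR-17 to miR-92 targets and the counts of other splits were set before their values were computed; the tests of zinc finger uptake and of that target list without members of the 22 lists were chosen after the result was seen.

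A hypothesis came from looking at the top genes of AGO2 IP against IgG IP in replicate 1: AGO2 RNA may hold targets of miRNAs abundant in T cells. A list of reported targets of the miR-17 to miR-92 cluster, written without 5 top genes already seen, had 45 of 54 genes kept, with a median of 0.32 against -0.12 for the other genes, 35 above 0, 18 called higher and 1 lower. ZNFX1 (3.47), ZBTB4 (3.25), TXNIP (2.67) and TNRC6A (2.60) were highest, ANKH (-0.92) and BMPR2 (-0.96) lowest. The camera p was 4.8e-07, but p = 0.294 with an estimated correlation; against reported targets of tissue-restricted miRNAs (29 genes kept, median -0.17) the medians differed by 0.489 (permutation p = 0.00984). Values of 7 of its genes, TNRC6A and BMPR2 among them, had been tabulated before as members of the 22 lists. Without those, 38 genes gave a median of 0.31, camera p = 6.1e-06, p = 0.316 with an estimated correlation and permutation p = 0.00588. Both permutations shuffled genes between the 2 target lists as if they were independent, so their p does not measure spread between samples. The result rests on replicate 1, since the median in replicate 2 was -0.03. Uptake of zinc finger mRNAs by both purifications alike was not decided: the list's median in replicate 1 was -0.198 in IgG IP and 0.0828 in AGO2 IP against the same Total RNA arrays, which restates the difference between the antibodies.

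Other splits of the same arrays were counted for each comparison of at least 3 arrays per group, in fits of its arrays alone. For AGO2 IP against Total RNA with the block, 1 of 34 splits, the real one, gave as many genes (3143, highest other 0), and for IgG IP against Total RNA 1 of 34 (1383, highest other 0). Since the replicate numbers pair the arrays, the like-for-like splits are the 18 with as many arrays of each replicate on both sides. Among these 18 the real one alone gave as many in both comparisons, but 18 are too few for a share under 0.05. Without the block, 2 of 35 splits gave as many for AGO2 IP against Total RNA (125, highest other 8073, the split by replicate number), so chance is not excluded there. Where the real count is 0, each split gives as many by construction, and the count says nothing about chance. This holds for IgG IP against Total RNA without the block (35 of 35, highest other 9197, again by replicate number). It also holds for AGO2 IP against IgG IP, with 35 of 35 splits without the block (0, highest other 8708, by replicate number) and 34 of 34 with it (0, highest other 3953). The latter split set both IgG IP arrays of replicate 1 with both control vector IP arrays of replicate 2, which is the exchange of 2 labels weighed above, and points to a structure of the samples. It holds too for the construct over the 3 fractions, with 100 of 100 splits without the block (0, highest other 4508) and 100 of 100 with it (0, highest other 0).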
